A study of Caenorhabditis elegans with 2 samples.

How the data were processed

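The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the nematode Caenorhabditis elegans. Per the labels, the worms carried an integrated transgene that expresses SPR-1 with a green fluorescent protein and FLAG tag at its C-terminus, and chromatin was precipitated with an antibody against green fluorescent protein. Whole hermaphrodites were collected as L4 larvae 50 hours after synchronisation by starvation at the L1 stage, and chromatin was fragmented by sonication. There was 1 group of 2 samples, which the labels call biological replicates 1 and 2 with a biosample of their own each. No untreated, mutant or untagged group was among the samples, so every comparison was made between regions or genes within the group.

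The deposited lists hold regions, not reads. Per the labels, they were made on the builds ce10 and ce11. For each build there was a list of candidate regions and background for each replicate, a list made from both replicates together (the pooled list), and a thresholded list. Per the deposited text listings, the candidate lists were the input of an analysis of the irreproducible discovery rate, which ranks regions by how well replicates match, and the lists were made with 1 control alignment per build. The control was not used here. The aligner, the peak caller and the threshold are not given in the sources used here. The signal value of each region is the authors' own, on a scale that is not given in the sources used here. It was used to rank and describe regions within a list, and its level was not compared between lists. The deposited −log10 q values were tied at the highest value for 92.6% of the thresholded regions on ce11, so they were not used for ranking. Read depth is unknown, and no interval that needs it is given. Intervals over regions or genes treat those as independent, which neighbouring regions and genes that share a promoter are not.

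The main results use the ce11 lists. The highest region end on each chromosome lay within the length of that chromosome in the reference genome WBcel235, which is the same build under another name, and genes were taken from Ensembl annotation release 115. No coordinate was converted between builds, and the ce10 lists entered as an alternative for results that need no annotation. Coordinates are 1-based. The 1686 lines of the thresholded list were the 1686 lines of highest signal in the pooled list of 30000. They described 1656 intervals, since an interval with several summits has a line for each. Lines on the mitochondrial genome, 23 in the thresholded list, were left out of every comparison of location, genes or sequence, which leaves 1663 nuclear lines.

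Comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Replicates were compared by the share of the 1686 strongest regions of replicate 1 that overlap by at least 1 bp a region among the 1686 strongest of replicate 2, against 1000 random draws of as many candidates of replicate 2. Spearman and Pearson correlations of log2 signal were computed over thresholded regions that overlap a candidate of each replicate, with 100000 shuffles. For location, a candidate counted as thresholded when a thresholded summit lay in it, and candidates that did and did not were compared by Fisher's exact test, two-sided. Candidates overlap, so 2276 nuclear candidates counted as thresholded, of which 1663 were lines of the thresholded list. The remainder only overlap such a summit, and candidates that hold the same summit are not independent. Autosome centres were the middle of 3 equal parts of each autosome by length. Summits were classed in the order promoter (within 500 bp of the start of a protein-coding gene), coding exon, untranslated region, intron and intergenic, and the 5 tests were adjusted by the Benjamini-Hochberg method. Summits were also set against 1000 random placements on the same chromosome.

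A protein-coding gene counted as bound when a thresholded summit lay within 1000 bp of its annotated start. The 25 gene lists were tested by Fisher's exact test against the other protein-coding genes with any pooled candidate summit within 1000 bp, with Benjamini-Hochberg adjustment over the lists. Annotated gene starts in this species are often trans-splice sites, which lie downstream of the start of transcription. Genes of 4 RNA classes counted as bound when a thresholded summit lay within 200 bp of the gene, against genes of any type with a candidate within 200 bp. Candidates within 20 kb of spr-1 and of unc-119, the genes named in the strain's description, were counted and set against all 19973 nuclear protein-coding genes. All 2080 words of 6 bases, a word and its reverse complement taken as the same, were counted within 50 bp of nuclear thresholded summits and in stretches 200 to 250 bp away on both sides, with exact McNemar tests and Benjamini-Hochberg adjustment. Odds ratios have 95% Woolf intervals, and 0.5 was added to each cell where a cell was 0. The threshold was 0.05.

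Named genes were those nearest the 10 thresholded regions of highest signal, up to 4 bound members of highest signal in each list past the threshold and up to 2 in each other list, and 11 genes of the SPR-1 and Notch pathways and the transgene. The 10 highest regions were all mitochondrial, so nuclear regions of highest signal, RNA genes and other genes outside this rule are named too, chosen after their values were seen.

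Alternatives were each replicate left out, in which case the 1686 strongest regions of the other replicate took the place of the thresholded list and its own candidates were the background, the 843 strongest thresholded regions, the 3372 strongest pooled candidates, other distances, transcript starts, backgrounds and overlap rules, and a comparison of 6-mers with candidates matched for GC content. The tests were tried on simulated data. The chaperone list, with 49 tested genes and a simulated odds ratio of 4, passed the threshold in 88.0% of 200 simulations over 9153 genes. Of the unchanged lists, 0.0833% passed. Smaller lists, such as the Notch list with 16 tested genes and the CoREST list with 8, were not simulated this way. How often such a rise would be found in them is unknown. An odds ratio of 1.5 for X was called in 100% of 200 simulations over 29977 candidates, and an odds ratio of 1 in 7.5%. Each candidate was called independently there, whereas overlapping candidates in the data are called together. A word planted in 12% of simulated summits came out 12.6 percentage points above the flanks. That was 1 run on random sequence with the same base shares at summits and flanks. It cannot show how the word test behaves where GC content differs between them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. All per-sample columns of the lists were mapped to a sample, and 0 were left over.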

Results

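SPR-1 is the C. elegans counterpart of CoREST, a corepressor that works with the histone demethylase LSD1 and histone deacetylases, and spr genes were found as suppressors of presenilin mutants. Regions called in the ChIP of tagged SPR-1 in L4 hermaphrodites were described from 2 biological replicates, 1 pooled candidate list and 1 thresholded list. No list from an untagged strain was at hand. A gene called bound below therefore has a thresholded summit nearby, which may or may not be specific binding by SPR-1. Replicate 1 had 26070 candidate regions and replicate 2 had 21966, while the pooled list had 30000. The thresholded list held 1686 summits, with a median width of 460 bp. Read depth is unknown. Per-replicate shares below come from each replicate's own 1686 strongest regions. All positions are on ce11 (WBcel235).

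The replicates ranked largely the same regions at the top. Of the 1686 strongest regions of replicate 1, 1194 (70.8%) overlapped a region among the 1686 strongest of replicate 2, and 98.0% overlapped any candidate of replicate 2. Random draws of candidates gave 10.7% on average and 13.0% at most (one-sided permutation p = 0.001, the smallest that 1000 draws can give). The promoter of the ribosomal protein gene rpl-3 held the strongest nuclear region, at rank 11 in replicate 1 and rank 15 in replicate 2, behind mitochondrial regions in each. A CoREST-family promoter further down, that of rcor-1, was at rank 865 in replicate 1 and 1581 in replicate 2. Across the 1682 thresholded regions with a candidate in each replicate, log2 signal correlated with Spearman's rho = 0.662 and Pearson's r = 0.844 (permutation p = 1e-05 for each, the smallest that 100000 shuffles can give). Over nuclear regions alone, an alternative chosen after seeing the data, rho was 0.648 and r was 0.768. These correlations are across regions, which are not independent replicates, and several lines can match the same replicate region. The thresholded list was itself made from these replicates, so the shuffles are not an independent test of their agreement.

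**Figure D1:**
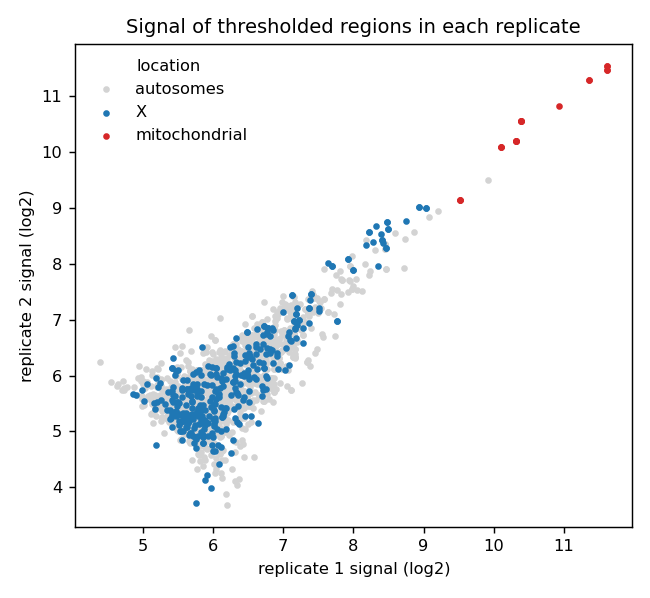
Log2 signal of each thresholded region in replicate 1 (horizontal axis) and replicate 2 (vertical axis), each point a region coloured by location. Mitochondrial regions sit at the top right, and the 1682 regions follow a common trend with Spearman's rho = 0.662.

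Many of the strongest nuclear regions lay at promoters of ribosomal protein and other housekeeping genes, sites on X far from gene starts, and spliced leader RNA genes. The region at III 3867277 to 3867844, with a signal of 1684, lay 278 bp upstream of rpl-3 (WBGene00004414). The next, at IV 4749869 to 4750273 (signal 1081), lay between rpl-20, 285 bp upstream of its start, and Y17G9B.5. The promoters of rpl-15 (IV 654694 to 655147, signal 1001), tasp-1 (III 10759033 to 10759460, signal 849), and cdc-48.1 (II 10563406 to 10563760, signal 782) were also among the 10 strongest nuclear regions. cdc-48.1 encodes an AAA ATPase that extracts ubiquitylated proteins. On X, a region at 11093845 to 11094448 (signal 1043) was intergenic and 4000 bp from the nearest protein-coding gene start, that of W02H3.3. A region at X 6296253 to 6296911 (signal 1008) lay in an intron, 3370 bp from the start of cest-16. The other X regions among the 10 strongest were intergenic, near K02D3.1 (13700587 to 13701125, signal 868), ZK899.6 (9465602 to 9466088, signal 781) and nspc-17 (14525546 to 14526296, signal 759). Another, at X 8036065 to 8036848 (signal 679), lay 4866 bp upstream of xol-1, the switch gene of sex determination.

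X held more of the thresholded regions than its share of candidates. Of 2276 nuclear candidates that held a thresholded summit, 477 (20.96%) were on X, against 4494 of 27701 others (16.2%), an odds ratio of 1.37 (95% interval 1.23 to 1.52, Fisher's exact p = 1.4e-08). Of the 1663 nuclear lines of the thresholded list itself, 352 (21.2%) were on X. With only those lines as thresholded, chosen after seeing the data, the odds ratio was 1.38 (1.22 to 1.56). Each replicate's own strongest nuclear lines had 19.9% ± 0.629 on X (mean ± SD, n = 2). Among the 50 strongest nuclear regions, 18 were on X in the pooled list, 17 in replicate 1 and 18 in replicate 2, while of the next 50 there were 8, 10 and 9. In a split chosen after seeing the data, candidates more than 500 bp from a gene start had an odds ratio of 1.67 (1.47 to 1.89) for X, and those nearer had 1.11 (0.905 to 1.35). The ratio of these odds ratios was 1.51 (1.19 to 1.91). With replicate 2 alone the odds ratio was 1.11 and the call was lost (Fisher's exact p = 0.0683). Of the lowest-ranked candidates of that replicate, 17.8% were on X, against 15.6% in replicate 1. Without candidates within 200 bp of a tRNA gene, which was chosen after seeing the data, the odds ratio was 1.05 (0.930 to 1.19, Fisher's exact p = 0.427).

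**Figure D2:**
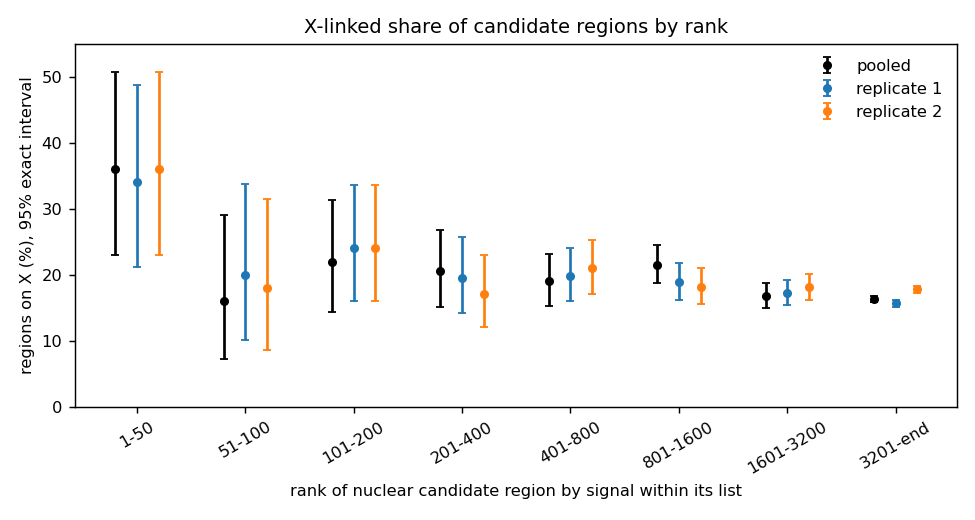
Percent of nuclear candidate regions on X (vertical axis) by rank of signal within each list (horizontal axis), for the pooled list and each replicate, with 95% exact binomial intervals. The 50 strongest regions had 36.0% on X in the pooled list, the next 50 had 16.0%, and the lowest-ranked pooled bin had 16.3%, so the share did not fall evenly with rank.

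On autosomes, central regions were slightly more common among thresholded candidates than among others. Of 1799 thresholded autosomal candidates, 724 (40.2%) lay in chromosome centres, against 37.3% of the others, an odds ratio of 1.13 (1.03 to 1.25, Fisher's exact p = 0.0123). The call was lost with replicate 2 alone, where the odds ratio was 1.08 (Fisher's exact p = 0.129). It was also lost among the 843 strongest regions (1.14, Fisher's exact p = 0.0570) and, in an alternative chosen after seeing the data, with only the candidate lines that are themselves thresholded (1.10, 0.977 to 1.23). Chromosome V had the fewest thresholded summits per megabase (10.6), and III the most (20.5), with X at 19.9.

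Promoters were the most common place of thresholded summits, and coding exons were the most under-represented place. Of the 1663 nuclear thresholded summits, 701 (42.2%) lay within 500 bp of a protein-coding gene start, 515 (31.0%) were intergenic, 351 (21.1%) were in introns, 50 (3.01%) in coding exons and 46 (2.77%) in untranslated regions. Each replicate's strongest regions had 42.6% ± 0.910 of summits near gene starts (mean ± SD, n = 2). Random placements gave 18.3% near gene starts on average and 21.4% at most (one-sided permutation p = 0.001, the smallest that 1000 draws can give). They gave 29.7% intergenic (26.1 to 33.6 over the draws) and 3.18% in untranslated regions (1.86 to 4.63), ranges that hold the observed shares. Against other candidates, the odds ratio was 2.22 for promoters (2.03 to 2.43, Fisher's exact adjusted p = 4.1e-66) and 1.42 for intergenic places (1.30 to 1.56, adjusted p = 3.9e-13). It was 0.186 for coding exons (0.151 to 0.229, Fisher's exact adjusted p = 2.6e-92), 0.678 for introns (0.611 to 0.753) and 0.612 for untranslated regions (0.486 to 0.772). The difference for untranslated regions was lost among the 3372 strongest candidates, with an odds ratio of 0.966 (Fisher's exact adjusted p = 0.661).

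Genes for cytosolic ribosomal proteins, translation factors, chaperones and the respiratory chain were bound more often than other genes. A total of 1164 protein-coding genes were bound, 12.7% of the 9153 with a candidate nearby, and each replicate's strongest regions bound 1160 ± 44.5 (mean ± SD, n = 2). Among cytosolic ribosomal protein genes, 48 of 78 (61.5%) were bound, an odds ratio of 11.4 (7.20 to 18.1, Fisher's exact adjusted p = 8.0e-23), with rpl-3, rpl-20, rpl-15 and rpl-35 (signal 757) the strongest. Replicate 1 alone bound 48 of them and replicate 2 alone 46. Heat shock and chaperone genes had 19 of 49 bound (odds ratio 4.40, 2.47 to 7.85, Fisher's exact adjusted p = 4.5e-05). They were led by the mitochondrial chaperonin hsp-60 (signal 549), the cytosolic chaperonin subunit cct-8 (440) and the DnaJ genes dnj-13 (343) and dnj-9 (329). Among translation factors, 12 of 36 were bound (3.46, 1.72 to 6.93, Fisher's exact adjusted p = 0.00939), among them iff-2 (signal 460), eif-3.C (353), eef-1G (227) and eef-2 (210). Respiratory chain genes had 11 of 35 bound (3.17, 1.55 to 6.48, Fisher's exact adjusted p = 0.0191), led by the cytochrome oxidase genes cox-5A (signal 635) and cox-5B (385), the ATP synthase gene atp-1 (329) and cyc-1 (178). Assigning each summit to its nearest gene ended the call for chaperones, at an odds ratio of 2.19 (Fisher's exact adjusted p = 0.223). The call for respiratory genes was lost among the 3372 strongest candidates, at 2.33 (Fisher's exact adjusted p = 0.0809).

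Chemoreceptor genes were bound less often. Of 164 with a candidate, 10 (6.10%) were bound, an odds ratio of 0.441 (0.232 to 0.838, Fisher's exact adjusted p = 0.0437). Most of the 1293 listed genes had no candidate nearby, and against all protein-coding genes the odds ratio was 0.118 (Fisher's exact adjusted p = 2.0e-21). The strongest were sre-23 (signal 242), sri-5 (202), srh-16 (183) and srh-269 (162). The call was lost when genes were bound only within 500 bp (0.497, Fisher's exact adjusted p = 0.266), with the nearest gene only (0.541, adjusted p = 0.277), and among the 843 strongest regions (0.334, adjusted p = 0.0583).

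**Figure D3:**
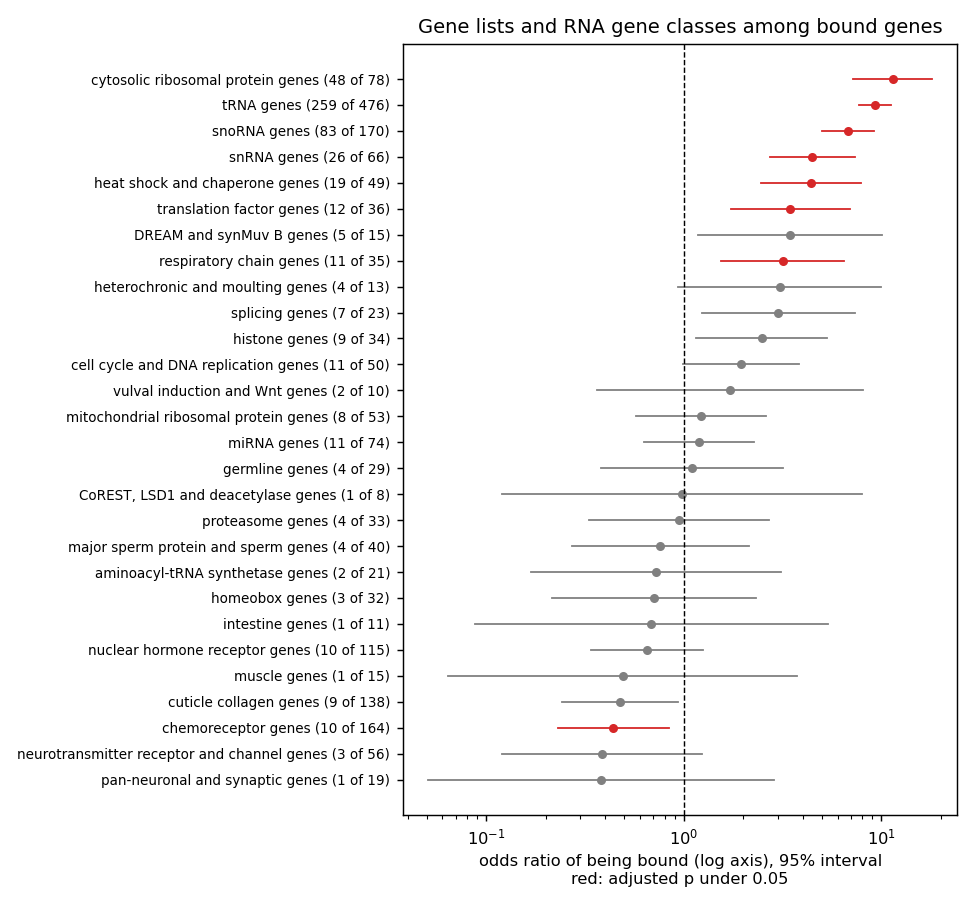
Odds ratio of being bound (horizontal log axis) with its 95% interval, for each gene list with a bound member and each RNA gene class (vertical axis, with bound and tested genes). Red marks an adjusted p under 0.05, and cytosolic ribosomal protein genes (48 of 78) and tRNA genes (259 of 476) lie furthest to the right.

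The other 20 lists did not pass the threshold after adjustment. The DREAM and synMuv B list, which includes the gene of the retinoblastoma protein, had 5 of 15 genes bound (odds ratio 3.44, 1.17 to 10.1, Fisher's exact adjusted p = 0.0919). These were lin-54 (signal 533, at a promoter shared with the ribosomal protein gene rpl-12), lin-53 (355) and, named after their values were seen, lin-9 (301), lin-35 (159) and efl-1 (118.8). That list passed among the 843 strongest and the 3372 strongest regions, and with all protein-coding genes as background, and had 3 of 12 bound with the nearest gene only (Fisher's exact adjusted p = 0.277). Histone genes had 9 of 34 bound, led by his-37 (signal 457), splicing genes 7 of 23, among them rsp-1 and rsp-2 at a shared promoter (175), and cell cycle genes 11 of 50, with cdc-48.1 and the sliding clamp gene pcn-1 (287) strongest. Histone genes passed with replicate 1 alone, among the 3372 strongest candidates and within 2000 bp, splicing genes within 2000 bp and with all genes as background, and cell cycle genes among the 843 strongest regions and with all genes as background. Heterochronic and moulting genes had 4 of 13 bound (lin-66, signal 154, and lin-46, 112, the strongest), and passed with all genes as background. Mitochondrial ribosomal protein genes had 8 of 53 (mrpl-23, 168, and mrpl-28, 152), germline genes 4 of 29 (mex-1, 195, and cgh-1, 139), and proteasome genes 4 of 33 (rpn-3, 219, and pas-5, 132). Aminoacyl-tRNA synthetase genes had 2 of 21 (ears-2, 252, and aars-1, 127). Vulval induction and Wnt genes had 2 of 10, egl-17 (signal 205) and sem-5 (105).

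None of the lists of single tissues, neuronal genes or transcription factors below passed the threshold. Cuticle collagen genes had 9 of 138 bound (odds ratio 0.475, 0.241 to 0.936, Fisher's exact adjusted p = 0.0919), with col-85 (signal 170) and col-185 (134) strongest. Replicate 1 alone bound 15 of them and replicate 2 alone 16, at odds ratios of 0.821 (0.479 to 1.41) and 0.846 (0.498 to 1.44). Among the 3372 strongest candidates the odds ratio was 1.19 (0.805 to 1.74), and among the 843 strongest regions it was 0.196 (Fisher's exact adjusted p = 0.0229). Major sperm protein and sperm genes had 4 of 40 (spe-48, 215, and spe-15, 164), muscle genes 1 of 15 (unc-60, 102), and intestine genes 1 of 11 (asp-1, 91.4). Pan-neuronal and synaptic genes had 1 of 19 (syd-2, 101), homeobox genes 3 of 32 (ceh-38, 192, and ceh-99, 100.4), and nuclear hormone receptor genes 10 of 115 (nhr-68, 215, and nhr-47, 198). Neurotransmitter receptor and channel genes had 3 of 56 (odds ratio 0.387, 0.121 to 1.24), with twk-5 (240) and glr-6 (115) strongest. Replicate 1 alone bound 5 of 54 of them (0.682) and replicate 2 alone 5 of 52 (0.585). With all genes as background they passed as lower.

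Genes of SPR-1 partners and of the Notch pathway had 1 bound member in all. Of the 8 genes of the CoREST, LSD1 and deacetylase list with a candidate nearby, only rcor-1 was bound (signal 101, I 26979 to 27438, 428 bp upstream of its start; odds ratio 0.980, Fisher's exact adjusted p = 1.0). These 8 include the histone methyltransferase genes met-2 and set-2. None of the 16 Notch and presenilin genes with a candidate was bound, in the pooled list or in either replicate's strongest regions (Fisher's exact p = 0.250, adjusted p = 0.461). The presenilin genes hop-1 and sel-12 had candidates with signals of 26.3 and 28.0, below the lowest thresholded signal of 79.7. The Notch receptor gene glp-1 had one at 21.04, and lin-12 had no candidate within 1000 bp. The zinc finger genes spr-3 and spr-4 had candidates at 27.7 and 30.3, the LSD1 gene spr-5 at 25.01 and the deacetylase gene hda-1 at 59.1, none of them thresholded, while lsd-1 and spr-1 had none.

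Genes for tRNA, snoRNA and snRNA were bound more often than other genes, and those for microRNA were not called. Of 476 tRNA genes with a candidate within 200 bp, 259 (54.4%) were bound, against 11.4% of other genes, an odds ratio of 9.26 (7.68 to 11.2, Fisher's exact adjusted p = 1.2e-108). On X, 124 of 215 (57.7%) were bound, and on autosomes 135 of 261 (51.7%). Many tRNA genes have near-identical copies, and how reads shared between copies were placed is not given in the sources used here. A tRNA gene lay within 200 bp of 240 (14.4%) of the nuclear thresholded summits, at a median rank of 836.5. Of snoRNA genes, which guide modification of ribosomal RNA, 83 of 170 were bound (odds ratio 6.75, 4.98 to 9.16, Fisher's exact adjusted p = 3.5e-30). Of snRNA genes, which in this annotation include the spliced leader RNAs, 26 of 66 were bound (4.48, 2.72 to 7.35, Fisher's exact adjusted p = 6.6e-08). Those further than 1000 bp from the start of a bound protein-coding gene, a split chosen after seeing the data, had an odds ratio of 2.38 (1.22 to 4.66, Fisher's exact adjusted p = 0.0238). The spliced leader genes sls-2.1 (summit at II 5844840, signal 683), sls-2.2 (II 5543698, signal 654) and sls-2.4 (I 4172289, signal 588), named after their values were seen, were at nuclear ranks 15, 20 and 25. MicroRNA genes had 11 of 74 bound (1.19, 0.626 to 2.26, Fisher's exact adjusted p = 0.599). With replicate 2 alone the odds ratio for tRNA genes was 5.50, and with replicate 1 alone 9.03.

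No candidate region lay near spr-1 itself. Around this gene (V 8126663 to 8129352, minus strand), the pooled list held 0 candidates within 20 kb, where the median protein-coding gene had 12 and 3.74% of the 19973 genes had 0. Each replicate's list also held 0 there, as was so for 2.26% of genes in replicate 1 alone and 2.30% in replicate 2 alone. The nearest pooled summits were at V 8084792 and 8164054, 79.3 kb apart, against a median of 1461 bp between neighbouring summits, and 29 of 29971 gaps were longer. unc-119 (III 10902641 to 10908935), the marker gene of the strain, had 12 candidates within 20 kb, and 45.9% of genes had fewer. No thresholded summit lay within 20 kb of either gene, which held for 56.5% of genes.

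**Figure D4:**
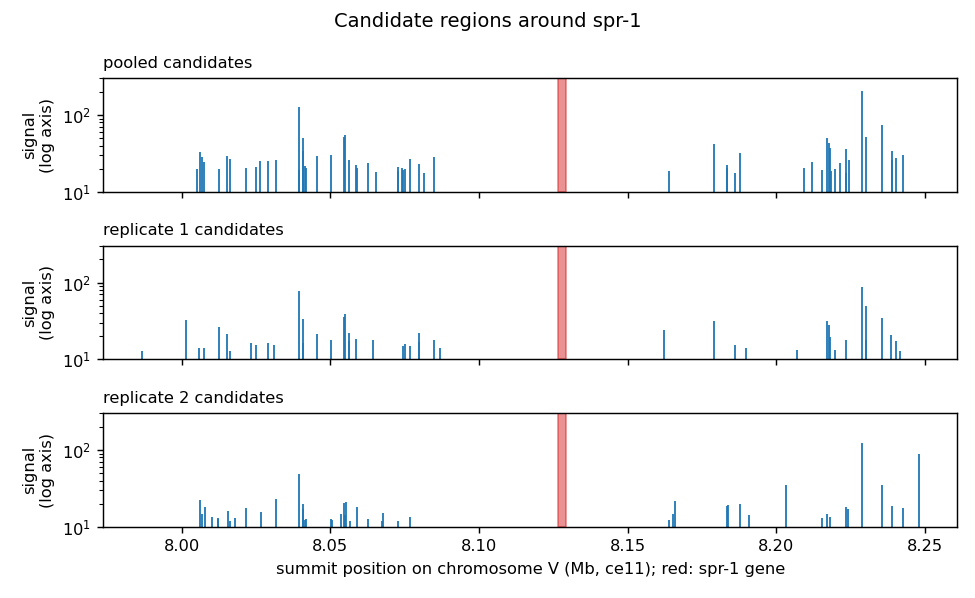
Signal of candidate regions (vertical log axis) by summit position on chromosome V (horizontal axis, Mb) in the pooled list and each replicate, with the spr-1 gene in red. No summit lies within 20 kb of the gene in any of the lists, and the pooled gap spans 79.3 kb.

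Summit sequences were rich in short GC-containing words. Of the 2080 words of 6 bases, 574 were more common within 50 bp of the 1663 summits than in the flanks and 396 less common. The words less common at summits by the most were AAAAAT (23.3% against 45.2%) and AAAATT (17.4% against 38.9%). The words more common by the most were GACGCA (14.6% of summits against 2.65% of flanks, exact McNemar adjusted p = 8.3e-34), ACGCAG (14.4% against 2.71%), GAGAGA (20.9% against 9.68%), AGACGC (13.0% against 2.65%) and CGTCTC (14.6% against 4.45%). GAGAGA was also among the 9 words fixed before the data were examined. Of the others, GCGCGA (5.41% against 1.68%), CCCGCC (5.77% against 2.29%), CACGTG (4.09% against 1.68%), CAGCAC (4.21% against 2.22%), GGACAG (3.49% against 1.68%) and CAGCTG (3.31% against 1.98%) passed the threshold. With replicate 1 alone the call was lost for CAGCAC (exact McNemar adjusted p = 0.0707) and GGACAG (adjusted p = 0.0679), as it was for GGACAG among the 843 strongest regions (adjusted p = 0.253) and for CAGCTG within 25 bp (adjusted p = 0.345). The GATA site GATAAG (3.91% against 4.39%) and TGGGAA (4.27% against 4.99%) did not. GC content was 47.8% within 50 bp of thresholded summits and 37.7% at other candidates. Against candidates matched for GC content, 42 words were more common, 38 of them among the 574. GACGCA and ACGCAG kept their call there, by 4.27 and 4.09 percentage points (Fisher's exact adjusted p = 0.0110 and 0.0166). AGACGC (2.83 points, Fisher's exact adjusted p = 0.148), CGTCTC (1.98, adjusted p = 0.453) and GAGAGA (1.68, adjusted p = 0.645) did not, nor did any other of the 9 words fixed before.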

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

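The thresholded list held 23 summits on the mitochondrial genome, which lie outside every comparison of genes or places. They are flagged because they lie outside those comparisons; no list from control samples was at hand to set the count against, so no test was made. All 23 mitochondrial candidates of the pooled list passed the threshold, and 19 of the 20 strongest thresholded summits were mitochondrial. Their signal ran from 212 to 6193, the strongest at position 4679. The 8 intervals covered 11173 of 13794 bp (81.0%), from position 747 to 12920. Replicate 1 had 21 mitochondrial summits and replicate 2 had 22, all among the 1686 strongest of their list. The 10 thresholded summits of highest signal lay nearest to genes that include COX3 and ND1. No explanation was tested.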

How the results depend on the processing

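Of 232 values recomputed under an alternative, 196 kept their direction and side of the threshold, or moved little. The ce10 lists changed none of the results they were used for. Promoters, coding exons, introns, intergenic places, tRNA, snoRNA and snRNA genes and ribosomal protein genes kept theirs under all alternatives run. Alternatives chosen only after seeing the data were the split of X by distance to gene starts, the strata of GC, the removal of tRNA genes, RNA genes away from bound promoters, nuclear regions for the correlation, and thresholded lines alone. With a replicate left out, the odds ratio of X ran from 1.11 to 1.40, that of autosome centres from 1.08 to 1.13, and the percent of genes with fewer candidates than unc-119 from 21.4 to 37.2. X had 1.11 within 500 bp of a gene start and 1.05 without tRNA genes. Autosome centres had 1.14 among the 843 strongest regions and 1.10 with thresholded lines alone, with the call lost in both, and untranslated regions 0.966 among the 3372 strongest candidates. With all protein-coding genes as background, 8 lists lay above it and 2 below, against 4 and 1, and 0 lay below at 500 bp or with the nearest gene only; the 1 below among the 843 strongest regions was the cuticle collagen list. MicroRNA genes away from bound promoters had an odds ratio of 0.949. Within 40 kb of spr-1, 1 candidate lay, and 0.956% of genes had fewer. Matching for GC left 42 words above background, 38 of them among the 574, and turned CACGTG to -0.18 and CAGCTG to -0.78 percentage points. GATAAG, past no threshold, ran from -0.90 to 0.30 points with a replicate left out, and TGGGAA from 0.36 to 0.60 against -0.72. Causes of these shifts under alternatives were not tested, except that removing tRNA genes or matching GC takes out the regions or difference it names. Explanations of some of the patterns are weighed further below. Agreement between replicates and the thresholded count need both replicates, so no replicate could be left out there. Unknown read depth limits any reading of regions missing from a list.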

Other observations

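The leading 6-mers AGACGC, GACGCA and ACGCAG overlap into the word AGACGCAG, which was counted after they were seen. It lay within 50 bp of 141 of 1663 nuclear thresholded summits (8.48%, 95% exact interval 7.18 to 9.92), in 0.962% of their flanks and at 1.51% of the 27701 other candidates. In candidates matched for GC content, counted after the rest, 6.43% held it (5.30 to 7.72), so the contrast was much smaller there. GC was matched over the same stretch, within 50 bp of the summit, in which the word was counted. The match therefore cannot tell whether GC content accounts for the contrast. Promoter summits had it in 8.99% and intergenic summits in 9.90%. Summits within 200 bp of a tRNA gene held it in 2 of 240 cases (0.833%), and those near bound ribosomal protein genes in 3 of 47. X had 5.97% and autosomes 9.15%. Around the strongest nuclear summit, at rpl-3, the sequence from III 3867556 to 3867596 was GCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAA. That stretch holds GACGCA, but AGACGCAG on neither strand.

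In the 3 patterns weighed next, the tests chosen only after the result was seen were the ratio of odds ratios for X, the odds ratio of X without the motif, the percent of genes with no candidate, the count of candidates near unc-119, the counts beside the gap, and the odds ratio of cuticle collagen genes. The ratio for X replaced a test on promoters alone that did not decide. For the gap at spr-1 the count near unc-119 was the first test of transgene copies, the test on the stretches beside the gap was added after it, and the percent of genes replaced a test on stretches of a length set by the gap itself. The test on tRNA genes was set before, for highly transcribed loci in general, and was narrowed to loci used in most cells after its result was seen.

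The excess of X among thresholded regions may come from tRNA genes. Of 612 nuclear tRNA genes, 276 (45.1%) lie on X, and without candidates within 200 bp of a tRNA gene the odds ratio of X fell from 1.37 to 1.05 (0.930 to 1.19). Higher depth or copy number over the whole of X might raise promoters and other places alike, and the ratio of their odds ratios was 1.51 (1.19 to 1.91). That ratio cannot decide on depth, since tRNA genes were not taken out of it. The places also pass the threshold at unlike rates, 924 candidates against 6519 others near gene starts and 1352 against 21182 further away. Most of the strongest X sites were not at tRNA genes. Of the 100 strongest nuclear summits, 26 were on X, and only 4 on any chromosome lay within 200 bp of a tRNA gene. The motif core GCGCAGGG is known from recruitment sites of the dosage compensation complex on X. Among the 100 strongest nuclear summits, it lay within 100 bp of 11 of 26 on X and 1 of 74 on autosomes. Of thresholded candidates, overlapping ones counted separately, 16 of 477 on X and 7 of 1799 on autosomes held it. Its odds ratio in thresholded against other candidates was 13.0 (6.10 to 27.6) on X. On autosomes it was 5.33 (2.21 to 12.9), so the rise was not confined to X. Candidates with the motif were too few to carry the excess of X, since the odds ratio of X without them was 1.33 (1.20 to 1.48). Whether SPR-1 itself or accessible chromatin gives signal at such sites was not tested.

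The stretch without candidates around spr-1 may have arisen by chance or not. In the pooled list, 3.74% of protein-coding genes had no candidate within 20 kb, too few to call common and too many to exclude. The share was 2.26% in replicate 1 alone and 2.30% in replicate 2 alone, and 9.47% within 10 kb in the pooled list. Genes that share an empty stretch are counted separately there. Of 10000 random stretches of the gap's length, 82 were empty, but that length was set by the gap itself. The gap was not poor in gene starts, with 20 against a median of 15 in random stretches. Chemoreceptor genes such as str-90 and str-129 were among them. Of the listed chemoreceptor genes, 164 of 1293 had a candidate within 1000 bp, against 9153 of all 19973 protein-coding genes. The count of starts cannot tell whether the gap holds genes that rarely have candidates. A candidate explanation is technical: extra copies of the stretch, carried by the transgene, may raise the control, or a filter on piled-up reads may have removed it. This stays open, since the 40 kb to the left of the gap held 17 candidates and the 40 kb to its right 5, against a median of 11 and a 5th percentile of 1, and a local gap would follow from many other causes too. Copies of both genes in the strain stay open as well, with 12 candidates within 20 kb of unc-119 against a median of 12, but 9 against 11 in replicate 1 and 5 against 9 in replicate 2; control reads that could decide were not analysed here, nor was a biological explanation tested.

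The binding of ribosomal protein, chaperone, translation factor and respiratory chain promoters may reflect raised signal at highly transcribed loci used in most cells, as tRNA genes also had it, with an odds ratio of 9.26 (7.68 to 11.2). Other genes used in most cells were not called, with odds ratios of 0.946 (0.332 to 2.70) for proteasome genes, 0.722 (0.168 to 3.10) for aminoacyl-tRNA synthetase genes and 1.22 (0.574 to 2.60) for mitochondrial ribosomal protein genes, intervals that allow a rise or none. Among the 3372 strongest candidates these were 1.51 (0.720 to 3.19), 0.818 (0.275 to 2.43) and 1.80 (1.01 to 3.18), none of them called after adjustment. Whether loci transcribed highly in a single tissue have raised signal cannot be told, since cuticle collagen genes had an odds ratio of 0.475 (0.241 to 0.936) in the pooled list, but 0.821 and 0.846 in single replicates and 1.19 among the 3372 strongest candidates. Over 5 bins of GC at each gene's strongest candidate, the odds ratio of ribosomal protein genes was 7.04 (4.21 to 11.8). The rise thus stayed when GC was compared between bins. Differences of GC within a bin remain, so how much of the rise goes with GC content is not settled. A ChIP of an untagged strain or of another tagged protein would separate SPR-1 from a general signal at such loci, and none was used here, so specific binding by SPR-1 stays open and untested.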
